A study of Mus musculus with 6 samples.

How the data were processed

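The study profiled RNA from haematopoietic stem cells of mice with and without obesity. Per the labels, bone marrow was taken at 4 months of age from C57BL/6 mice homozygous for the db mutation of the leptin receptor gene and from wild-type (WT) littermates. Red cells were lysed, the marrow was enriched for c-Kit, and lineage-negative Sca-1+ c-Kit+ cells that carried CD150 but not CD48 were sorted, 20000 cells per library, into a lysis reagent. The antibodies against lineage markers covered red cells, granulocytes, macrophages and lymphocytes. Total RNA was amplified, made into stranded poly(A) libraries and read as pairs of 75 nucleotides. The labels describe 3 independent experiments, each with 1 WT and 1 db/db library, so there were 6 libraries, 3 per group. The labels do not say whether a library came from 1 mouse or from several.

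The deposited values were TPM per gene symbol, a transcript abundance corrected for length and scaled to a fixed total, which the authors made with RSEM and Bowtie2 on the mm9 build, per the submitters' processing notes. Versions, settings and the gene annotation were not given in the sources used here. The table held 23955 symbols in 6 columns, 1 per library, and 8489 symbols were at 0 in every library. Each column summed to 1000000 over the symbols listed. TPM keeps no read depth, so the depth of each library is unknown and no counting interval or detection floor could be attached to a value. The error used is the spread between libraries, with no counting error. The limma test below pools each gene's spread with that of other genes, with 17.7 prior against 4 residual degrees of freedom. In RSEM, reads that match several near-identical genes are divided between them by an estimate, so such genes were treated as uncertain and their sum was given. Symbols were used as the file gave them. No coordinates are printed, because the reference annotation used here for transcript lengths and GC content was of a later mouse build than mm9.

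The comparison of db/db with WT was made with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), over the 11931 genes with a mean of at least 1 TPM, with genotype as the only term, empirical Bayes moderation with a trend, two-sided tests and Benjamini-Hochberg adjustment. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. A gene passed at an adjusted p under 0.05. Means are given as TPM ± SD. For Gfi1, which the title of the series names, and for Lepr, an exact two-sided permutation test over the 10 splits of the libraries was added. Gene lists were tested with camera from limma with its preset inter-gene correlation of 0.01 and adjusted over all lists. Camera with an estimated correlation and fry stand beside it. Of 31 lists fixed by name, 30 had at least 5 measured members. The list of mast cell, basophil and eosinophil genes had 3 and was not tested. The lists covered HSC identity, lineages and other marrow cell types, the cell cycle, metabolism, signalling and stress.

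The genes to name were set by a rule. It took Lepr and Gfi1. It took in each direction up to 12 genes of largest fold change among those that passed with the same sign in all 3 experiments. Free places were filled with genes of smallest unadjusted p under 0.05 with an absolute log2 fold change of at least 0.58 and the same sign in all 3 experiments, and these did not pass. From each list it took up to 3 members of smallest p and the member of highest mean. The groups, the tests, the lists, this rule and the alternatives named next were chosen before the data were examined.

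Those alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, moderation without a trend or with a robust prior, array weights, the experiment as a replicate block, each library left out in turn, and an adjusted p under 0.1. Others were added after the values were seen. They were removal of the 3 most abundant rRNA-like symbols (Rn45s, Gm20594 and Lars2), 1 row per set of identical rows, removal of transcript length or GC trends with and without the block, an estimated correlation with the block, a granulocyte gene score as a covariate, and the log2 size factor as a covariate. Trends were fitted to each library's deviations from the gene means with natural splines of 4 degrees of freedom, over the 99.3% of tested genes that had a length.

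The pairing comes from the labels, which give each experiment number to 1 WT and 1 db/db library. Across genes, the deviations from the group means correlated at 0.04, 0.01 and 0.16 in libraries of the same experiment and at -0.12 to 0.08 in libraries of different experiments. No library repeated another, since at most 0.654% of tested genes had identical values in any pair. On data simulated for this comparison over the same 11931 genes with 200 genes changed, in 5 runs, the test recovered 22.2% of genes changed by 1 on the log2 scale and 90% of those changed by 2. A share of 6.50% of its calls was false, and no unchanged list was called. The noise of each gene was drawn from a normal distribution with the spread that limma had moderated, and no shift of a whole library was added. The simulation thus assumed the model it tested, and its false share may not hold for the measured libraries. Changed genes were drawn only from the more abundant ones, so the recovered shares do not cover genes of low value. The simulated genes varied independently of each other, whereas the measured ribosomal protein list had an estimated correlation of 0.39. The simulation therefore cannot show how often camera with its preset correlation calls unchanged lists of correlated genes.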

Results

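Gene expression was measured by RNA sequencing in haematopoietic stem cells (HSCs) sorted as CD150+ CD48- lineage-negative Sca-1+ c-Kit+ cells from the marrow of 4-month-old mice. The db/db mice lack a working long form of the leptin receptor and become obese, and their littermates served as WT controls. Each of 3 experiments gave 1 library per genotype, so n = 3 in each group, and the values were TPM. Sequencing depth per library is unknown. Between 13314 and 13810 symbols were above 0 in each library. Median-of-ratios size factors of the TPM values ran from 0.815 in WT replicate 2 to 1.23 in db/db replicate 3. The 45S ribosomal RNA symbol Rn45s took 10.4%, 10.4% and 6.46% of the TPM in the WT libraries and 8.51%, 8.04% and 6.34% in the db/db libraries. The log2 values correlated across genes at 0.913 to 0.940 between libraries of a genotype and at 0.917 to 0.940 between genotypes, so the libraries did not separate by genotype on their whole profile.

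Lepr, the gene mutated in db/db mice, was listed at 2.34, 2.93 and 2.79 TPM in WT replicates 1, 2 and 3 and at 1.51, 2.44 and 2.04 TPM in the db/db libraries of the same experiments. The means were 2.69 ± 0.308 TPM (SD, n = 3) in WT and 2.0 ± 0.467 TPM (SD, n = 3) in db/db HSCs. The log2 fold change of -0.31 (SE 0.53) did not pass in limma (Benjamini-Hochberg adjusted p = 0.939). The exact two-sided permutation test gave p = 0.2, where the smallest value it can give for 3 against 3 libraries is 0.1. The db mutation is known to alter splicing of the long isoform, so a total TPM for the gene does not check the genotype. The 19 measured genes of a list of neighbours of Lepr on its chromosome were not called by camera (adjusted p = 0.682).

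The title of the series names Gfi1, a zinc-finger repressor that restrains HSC proliferation and is needed for neutrophil formation. Gfi1 was 3.54 ± 1.41 TPM (SD, n = 3) in WT and 13.1 ± 3.74 TPM (SD, n = 3) in db/db HSCs, a ratio of means of 3.69. Values were 1.99, 3.88 and 4.75 TPM in WT replicates 1, 2 and 3 and 11.8, 17.3 and 10.2 TPM in the db/db libraries, so db/db was higher in all 3 experiments and the groups did not overlap. The log2 fold change was 1.65 (SE 0.46), with differences of 2.09, 1.91 and 0.96 within the experiments. It did not pass over all genes in limma (Benjamini-Hochberg adjusted p = 0.435, unadjusted p = 0.00160). The exact two-sided permutation test gave p = 0.1, the smallest it can give. Among 19 measured genes on the list of Gfi1 and genes it is known to bind or repress, Gfi1 was the 1 gene that passed when adjusted over the list alone. Gfi1 was singled out because the title of the series that holds these libraries names it, so this pass is not independent support. The list as a whole was not called (camera adjusted p = 0.960). Cdkn1a, a cell-cycle inhibitor on that list, was 22.3 ± 13.7 TPM in WT and 43.2 ± 26.7 TPM in db/db, and the transcription factor Egr1 was 1223 ± 492 and 1546 ± 247 TPM (SD, n = 3 each).

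The remaining comparison asked which transcripts differed between db/db and WT HSCs over the whole table. Higher in db/db were I730030J21Rik, a non-coding transcript, the adult beta-globin gene Hbb-b2, and Ccl3, a chemokine also known as MIP-1 alpha. I730030J21Rik rose from 186 ± 23.6 to 796 ± 186 TPM (SD, n = 3 each), a log2 fold change of 2.07 (SE 0.24, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000175). Hbb-b2 rose from 74.5 ± 17.6 to 706 ± 571 TPM, by 2.93 (SE 0.39, adjusted p = 0.000688), and Ccl3 from 15.1 ± 10.3 to 131 ± 58.0 TPM, by 3.22 (SE 0.48, adjusted p = 0.00292). Each was higher in all 3 experiments. The differences within experiments were 3.90, 2.68 and 2.20 for Hbb-b2 and 3.07, 5.19 and 1.40 for Ccl3.

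In limma with Benjamini-Hochberg adjustment, 4 symbols passed as higher and 0 as lower among 11931 genes. The symbol Hbb-bt carried values identical to Hbb-b2 and counts as the same transcript. At an unadjusted p under 0.05, 489 genes were higher and 149 lower, 638 in all, where chance alone gives 597. The count of 4 rested on single libraries, since it was 16 without WT replicate 1 and 0 without db/db replicate 2, where 333 genes were higher and 122 lower at an unadjusted p under 0.05. The median log2 fold change of all genes was 0.18 on the TPM scale and 0.00 after median-of-ratios scaling, and the split at an unadjusted p under 0.05 was then 297 higher and 355 lower, or 304 and 383 after quantile normalization. Only I730030J21Rik passed under either scaling. After median-of-ratios scaling the log2 fold change of Hbb-b2 was 2.73 (adjusted p = 0.36, within a range over its 20 alternatives of 4.82e-05 to 0.890) and that of Ccl3 3.04 (0.339, within 0.000691 to 0.890 over 24), so both calls ended while the fold changes stayed near 2.93 and 3.22. I730030J21Rik passed in 21 of its 24 alternatives (adjusted p 1.22e-05 to 0.349) and not without db/db replicate 2 (0.0684). Hbb-b2 also missed without WT replicate 3 (0.0882) and without db/db replicate 2 (0.149), and Ccl3 without db/db replicate 1 (0.232) and replicate 2 (0.569). With the robust prior the limma adjusted p was 0.503 for Hbb-b2 and 0.317 for Ccl3, and without the trend no gene passed. Groups did not overlap for 1214 genes, 10.2% of those tested, where chance gives 10%, and 937 of these were higher in db/db and 277 lower.

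The next genes by unadjusted p that were higher in all 3 experiments did not pass. Gimap3, a GTPase of immunity-associated proteins expressed in lymphocytes, was 3.07 ± 2.14 TPM in WT and 18.8 ± 3.06 TPM in db/db HSCs, and P2rx7, an ATP-gated ion channel, was 4.51 ± 0.355 and 22.9 ± 5.39 TPM (limma adjusted p = 0.0649 for both). Spic, a transcription factor of red-pulp macrophages, was 2.73 ± 1.05 and 13.6 ± 0.893 TPM, and the leukocyte tetraspanin Cd53 was 16.2 ± 9.05 and 54.0 ± 18.9 TPM. The other 4 were Fcnb, Lcn2, Ifitm6 and Ly6c2, with log2 fold changes of 3.46, 2.76, 3.04 and 2.45 and adjusted p from 0.155 to 0.327. Fcnb was listed at 0 in WT replicates 2 and 3 and at 16.4 TPM in WT replicate 1, above its 15.6 TPM in db/db replicate 2. In experiment 1 the differences of Fcnb, Lcn2, Ifitm6 and Ly6c2 were 0.91, 0.60, 0.48 and 0.28, and in experiments 2 and 3 they ran from 3.08 to 5.42. Without WT replicate 1 all 4 passed in limma, Fcnb with a log2 fold change of 4.84 (adjusted p = 0.000144, within a range over its alternatives of 0.000144 to 0.998).

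No gene passed as lower. Rps27rt, a near-identical copy of the ribosomal protein gene Rps27, was listed at 2335 ± 1023 TPM in WT and 243 ± 396 TPM in db/db HSCs, a log2 fold change of -6.28 (SE 1.21, limma adjusted p = 0.0649). It was listed at 1155, 2885 and 2964 TPM in the WT libraries and at 0.01, 29.1 and 699 TPM in the db/db libraries, and its fold change was -3.89 without db/db replicate 1 and -8.60 without db/db replicate 3. Reads shared by the copies make its level uncertain, and the sum of Rps27 and Rps27rt was 11240 ± 2288 TPM in WT and 8156 ± 2564 TPM in db/db. Myl10, a myosin light chain gene, was 76.7 ± 38.4 and 20.3 ± 13.3 TPM (log2 fold change -1.92, SE 0.41, adjusted p = 0.139). With the experiment as a replicate block, Rps27rt and Myl10 both passed in limma (adjusted p = 0.0261 each), within ranges over 24 alternatives of 4.82e-05 to 0.998 and 0.00797 to 0.890. Scrn1 was 7.35 ± 2.21 and 0.337 ± 0.221 TPM (adjusted p = 0.117). S100a5 was listed at 1.43, 11.99 and 8.68 TPM in the WT libraries and at 0 in all 3 db/db libraries (adjusted p = 0.250). The remaining 8 named genes were Gm13546, Erp27, St3gal5, 2410015M20Rik, Epdr1, Creb5, Copz2 and Oas1a, with log2 fold changes from -2.45 to -1.14 and adjusted p from 0.334 to 0.437.

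**Figure D1:**
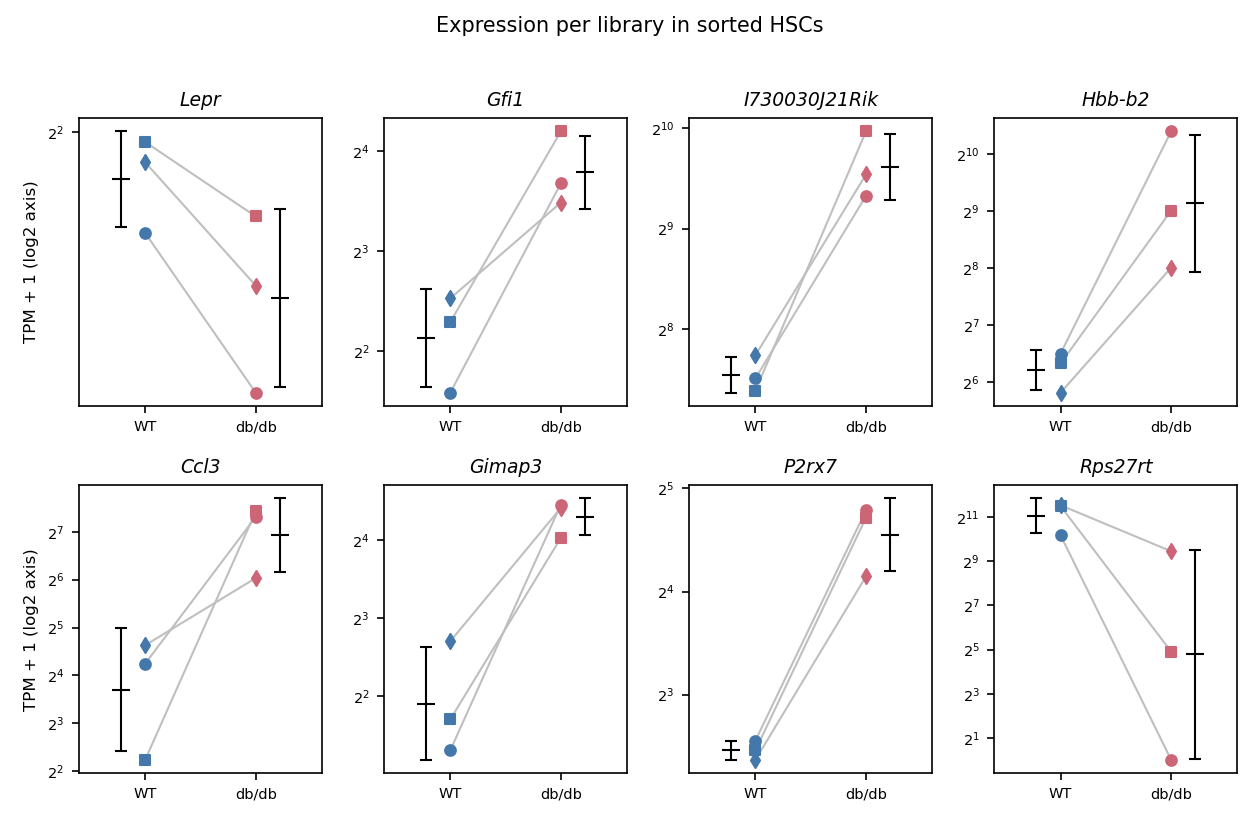
TPM + 1 on a log2 axis for 8 genes in the 3 WT (blue) and 3 db/db (red) libraries. Circles, squares and diamonds are experiments 1, 2 and 3, grey lines join libraries of an experiment, and the black marks beside the points are the mean ± SD of the log2 values. I730030J21Rik, Hbb-b2 and Ccl3 passed the test over all genes, while Gfi1 was higher in db/db in all 3 experiments and did not pass.

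Genes of progenitors that lie outside the HSC gate were called as higher in db/db HSCs by camera with its preset correlation (adjusted p = 0.000481), but not with an estimated correlation (adjusted p = 0.443) or by fry (adjusted p = 0.285). Of 18 measured members, 16 lay above the median of all genes and 2 below, with a list median of 0.57, 0.39 relative to all genes. Adjusted over the list alone, 4 members were higher and 0 lower, against 0 adjusted over all genes. Members of smallest p were Cd53, the granule protein gene Nkg7 at 78.4 ± 32.9 TPM in WT and 171 ± 40.3 TPM in db/db, and the cytokine receptor gene Flt3 at 9.17 ± 3.29 and 23.1 ± 5.80 TPM. The most abundant member, Cd27, was 219 ± 125 and 229 ± 84.9 TPM (SD, n = 3 each), did not pass, and was lower in db/db in experiments 1 and 3, by -0.49 and -0.05. The list shares Mpo and Ctsg with the granulocyte list below. The relative median was higher in db/db in all 3 experiments, by 0.43, 0.47 and 0.41. Over all libraries it moved to 0.22 without WT replicate 3, where the call ended (adjusted p = 0.0665, within a range over 27 alternatives of 2.34e-05 to 0.899), to 0.24 without db/db replicate 2 and to 0.68 without db/db replicate 3.

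Lymphoid genes were also called as higher by camera with its preset correlation (adjusted p = 0.00822), but not with an estimated correlation (adjusted p = 0.443) or by fry (adjusted p = 0.285). Of 11 measured members, 9 lay above the median of all genes, with a list median of 0.58, 0.40 relative to all genes, and 2 were higher when adjusted over the list alone. Thy1, a surface glycoprotein of T cells and some stem cells, was 13.9 ± 5.28 TPM in WT and 40.3 ± 12.2 TPM in db/db, Cd4 was 4.36 ± 2.80 and 10.8 ± 3.27 TPM, and Cd74, the invariant chain of antigen presentation, was 323 ± 175 and 358 ± 95 TPM (SD, n = 3 each). Flt3 is among the genes that stand on both this list and the progenitor list. The call also ended without WT replicate 3 (relative median 0.46, adjusted p = 0.0665), without db/db replicate 1 (0.14, adjusted p = 0.379), without a filter on low values (0.20, adjusted p = 0.153), with array weights (0.23, adjusted p = 0.0860) and with the granule gene score as a covariate (0.23, adjusted p = 0.106). The adjusted p ranged over 27 alternatives from 0.000496 to 0.899.

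Granulocyte and monocyte genes were called as higher by camera with its preset correlation (adjusted p = 0.00679), but not with an estimated correlation (adjusted p = 0.845) or by fry (adjusted p = 0.497). Of 28 measured members, 21 lay above the median of all genes, with a list median of 0.39, 0.21 relative to all genes. Of the 28, 6 were higher when adjusted over the list alone, and 12 with the replicate block. Lcn2, a secondary granule protein gene, was 54.6 ± 76.5 TPM in WT and 185 ± 59.7 TPM in db/db, and Ly6c2, a monocyte surface gene, was 7.54 ± 9.01 and 36.5 ± 27.9 TPM. S100a8, a calcium-binding protein gene of neutrophils, was 2127, 67.8 and 90.5 TPM in WT replicates 1, 2 and 3 and 1528, 559 and 512 TPM in the db/db libraries. WT replicate 1 thus stood apart from the other WT libraries. The mean log2 value of 5 granule genes (S100a8, S100a9, Ngp, Camp and Ltf) was 8.71, 4.10 and 4.46 in WT and 8.49, 7.07 and 7.08 in db/db, and in experiment 1 it was not higher in db/db. Without WT replicate 1, 12 further symbols passed over all genes in limma. They were Lcn2, S100a8, Fcnb, Camp, S100a9, Ngp, Ly6c2, Ltf, Ifitm6, Chil3 and Cd177, all higher, and S100a5, lower. The call also ended without WT replicate 3 (relative median 0.06, adjusted p = 0.659), db/db replicate 1 (0.38, adjusted p = 0.292) or db/db replicate 2 (0.20, adjusted p = 0.0868), and the relative median was -0.01 with array weights (adjusted p = 0.932) and -0.09 with the mean of the 5 granule genes, which are themselves on the list, as a covariate (adjusted p = 0.792). The relative median was 0.52 without WT replicate 1, 0.47 without WT replicate 2 and 0.76 without db/db replicate 3. It was 0.54 and 0.32 with pseudocounts of 0.1 and 0.5, and 0.33 without a filter on low values. At a mean of at least 5 TPM it was 0.85, and with the log2 size factor as a covariate 0.71. The adjusted p of the list test ranged over 27 alternatives from 1.71e-12 to 0.933.

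**Figure D2:**
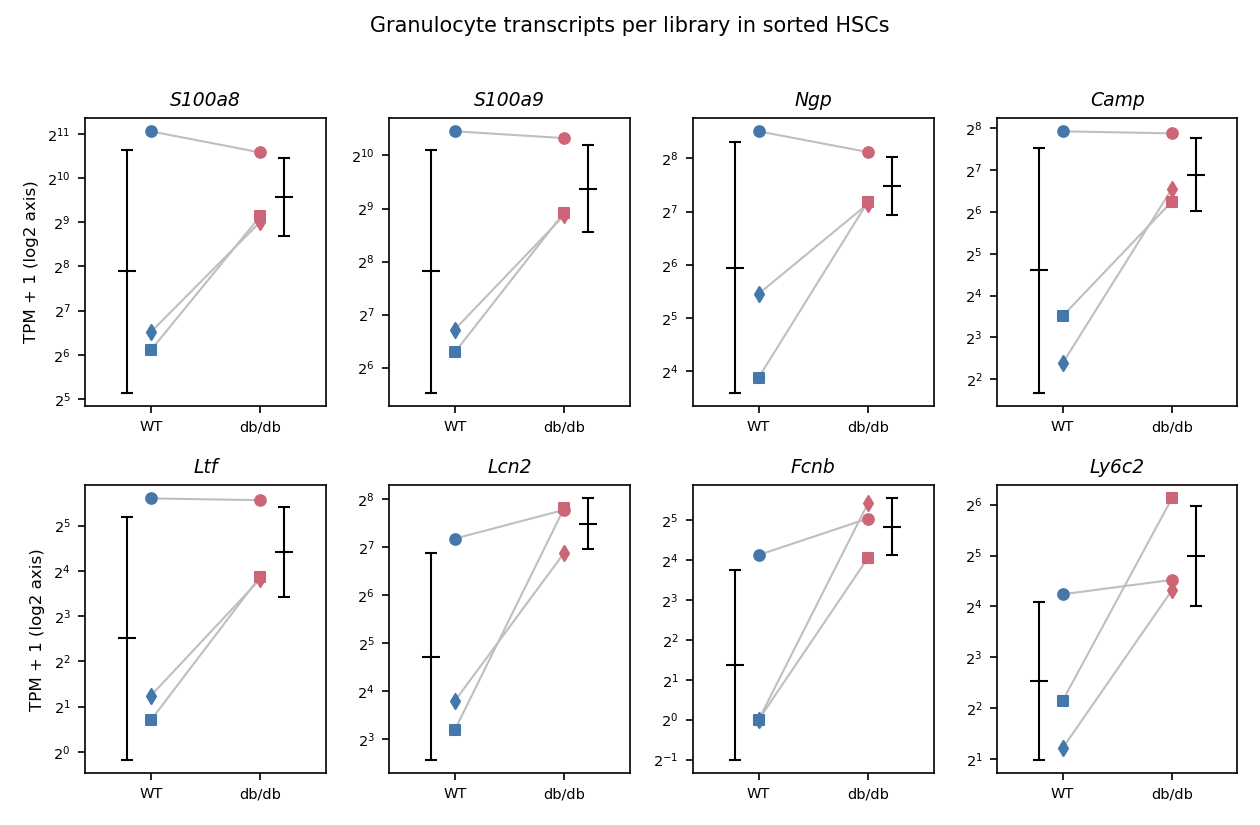
TPM + 1 on a log2 axis for 8 granulocyte and monocyte genes in the 3 WT (blue) and 3 db/db (red) libraries. Circles, squares and diamonds are experiments 1, 2 and 3, grey lines join libraries of an experiment, and the black marks beside the points are the mean ± SD of the log2 values. WT replicate 1 sits with the db/db libraries, at 2127 TPM for S100a8 against 67.8 and 90.5 TPM in WT replicates 2 and 3.

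Interferon response genes were called as lower in db/db HSCs by camera with its preset correlation (adjusted p = 1.56e-05), but not with an estimated correlation (adjusted p = 0.761) or by fry (adjusted p = 0.619). Of 32 measured members, 25 lay below the median of all genes, with a list median of -0.10, -0.28 relative to all genes. At an unadjusted p under 0.05, 5 were lower and 0 higher, and 0 passed when adjusted over the list alone, or 1 with the replicate block. Oas1a, an antiviral oligoadenylate synthetase, was 39.3 ± 9.02 TPM in WT and 16.0 ± 5.68 TPM in db/db, Ifi27 was 102 ± 37.9 and 50.1 ± 7.97 TPM, and the ubiquitin-like modifier Isg15 was 41.8 ± 25.3 and 18.9 ± 6.63 TPM. Isg15 differed mainly in experiment 1, by -2.54 against -0.30 and -0.20 in experiments 2 and 3, since WT replicate 1 was at 71.0 TPM and WT replicates 2 and 3 at 26.5 and 27.8 TPM. B2m, the light chain of MHC class I, was 5625 ± 1560 and 6347 ± 823 TPM (SD, n = 3 each). The relative median of the list was 0.25, 0.16 and 0.07 in the WT libraries and -0.11, -0.15 and -0.17 in the db/db libraries, without overlap. Leaving out any 1 library kept the call, and the adjusted p ranged over 27 alternatives from 8.25e-06 to 0.899.

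Ribosomal protein genes were called as lower by camera with its preset correlation (adjusted p = 1.21e-11), but not with an estimated correlation (adjusted p = 0.845) or by fry (adjusted p = 0.606). Of 82 measured members, 79 lay below the median of all genes, with a list median of -0.24, -0.42 relative to all genes. At an unadjusted p under 0.05, 12 were lower and 0 higher, and 0 passed when adjusted over the list alone. Rps28 was 3727 ± 650 TPM in WT and 2415 ± 971 TPM in db/db, Rplp1 was 5517 ± 1020 and 3597 ± 1359 TPM, and Rpl10 was 9336 ± 1371 and 10328 ± 638 TPM (SD, n = 3 each). The genes of this list made up 29.4%, 33.3% and 25.7% of the TPM in the WT libraries and 30.4%, 22.9% and 22.4% in the db/db libraries. Libraries with low size factors had the higher shares in both genotypes, and in experiment 1 the relative median was 0.02 higher in db/db, against -0.97 and -0.30 in experiments 2 and 3. Over all libraries the relative median shrank to -0.12 after quantile normalization (adjusted p = 0.0170), -0.23 without WT replicate 2 (0.00132) and -0.28 without db/db replicate 3 (0.000413). With the log2 size factor as a covariate it was -0.08 and the call ended (adjusted p = 0.235, within a range over 27 alternatives of 5.90e-21 to 0.933).

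Oxidative phosphorylation genes were called as lower by camera with its preset correlation (45 measured, adjusted p = 0.00308), but not with an estimated correlation (adjusted p = 0.443) or by fry (adjusted p = 0.537). Their median of 0.01 and mean of -0.08 differed in sign, and the median was -0.17 relative to all genes. At an unadjusted p under 0.05, 4 were lower and 0 higher, and 0 passed when adjusted over the list alone. Uqcrq, of respiratory complex III, was 278 ± 25.6 TPM in WT and 169 ± 40.1 TPM in db/db, Atp5e was 518 ± 101 and 313 ± 132 TPM, and Atp5b, also of ATP synthase, was 1874 ± 264 and 2274 ± 340 TPM (SD, n = 3 each). The relative median differed by 0.07 in experiment 1 and by -0.58 and -0.18 in experiments 2 and 3. The call also ended without WT replicate 2 (relative median -0.09, adjusted p = 0.287), without db/db replicate 3 (-0.19, adjusted p = 0.156), with the transcript length trend removed (-0.08, adjusted p = 0.153, or 0.164 with the replicate block) and with the log2 size factor as a covariate (-0.07, adjusted p = 0.548). The relative median was -0.29 without WT replicate 3 and -0.32 without db/db replicate 1, and the adjusted p ranged over 27 alternatives from 0.000176 to 0.899.

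**Figure D3:**
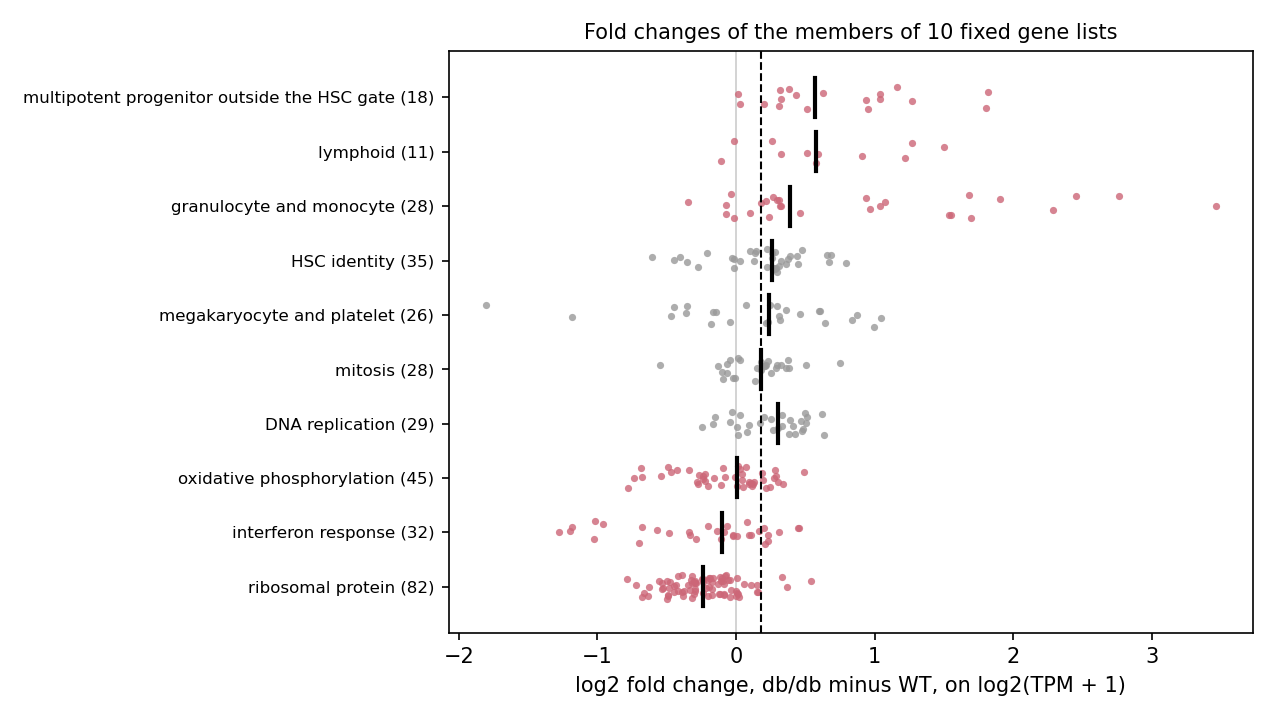
Log2 fold change of each measured member, db/db minus WT, for 10 of the gene lists, with the number of members in parentheses. Black bars are list medians, the dashed line is the median of all genes at 0.18, and red marks the 6 lists called by camera with its preset correlation. The medians of the progenitor, lymphoid and granulocyte lists lie to the right of the dashed line and those of the interferon, ribosomal protein and oxidative phosphorylation lists to its left, while each of these 6 lists has members on both sides.

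Genes of HSC identity were not called (35 measured, relative median 0.08, camera adjusted p = 0.772). Slamf1, which encodes the sorting marker CD150, was 17.8 ± 6.04 TPM in WT and 31.0 ± 7.17 TPM in db/db, and the transcription factor genes Erg and Lmo2 were 47.1 ± 24.7 and 68.9 ± 11.6 TPM and 715 ± 262 and 827 ± 266 TPM (SD, n = 3 each). None of the 35 passed when adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Proliferation genes were not called either, with adjusted p of 0.879 for mitosis and 0.424 for DNA replication. Pcna, the replication clamp, was 504 ± 96.3 and 679 ± 130 TPM. Lists of quiescence genes and of megakaryocyte and platelet genes both had an adjusted p of 0.682, and the latter held Thbs1, at 6.33 ± 2.1 TPM in WT and 1.07 ± 0.443 TPM in db/db, beside Plek, at 27.4 ± 2.90 and 51.8 ± 19.1 TPM.

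Erythroid genes were not called (15 measured, adjusted p = 0.120), although Hbb-b2, its copy Hbb-bt and Rhag were higher when adjusted over the list alone. Rhag, an ammonium channel gene of red cells, was 1.39 ± 0.425 TPM in WT and 7.54 ± 1.47 TPM in db/db, and the alpha-globin gene Hba-a1 was 13.5 ± 15.4 and 12.4 ± 10.4 TPM (SD, n = 3 each). Adjusted p was 0.0568 for adhesion and niche retention and 0.0735 for TGF-beta, BMP and Notch signalling, whose member Smad4 was 17.9 ± 6.04 and 32.0 ± 1.44 TPM. It was 0.424 for macrophage genes and 0.682 for stroma, endothelium and adipocyte genes. Cpa3, a mast cell protease gene, was 1.65 ± 0.892 and 10.4 ± 5.03 TPM, on a list too short to test.

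Metabolic lists other than oxidative phosphorylation were not called. Adjusted p was 0.682 each for antioxidant and Nrf2 target genes, glycolysis, and fatty acid oxidation with PPAR targets, and 0.424 for cholesterol and fatty acid synthesis. Ucp2, a mitochondrial carrier gene, was 236 ± 11.2 TPM in WT and 342 ± 6.96 TPM in db/db, and Gstm1, a glutathione transferase gene, was 690 ± 202 and 1118 ± 33.5 TPM (SD, n = 3 each). Leptin, insulin and FoxO signalling had an adjusted p of 0.518. Sesn3, a FoxO target, was 10.8 ± 2.60 and 24.2 ± 9.57 TPM, and Pik3ip1, an inhibitor of PI3 kinase, was 82.0 ± 22.0 and 133 ± 11.8 TPM. Stress and signalling lists gave 0.424 for TNF and NF-kB targets, of which Ccl3 was the 1 that passed, 0.682 for immediate early genes, 0.488 for heat shock and unfolded protein response, and 0.424 for p53 targets. Genes of aging HSCs gave 0.682, myosin, actin and polarity genes 0.424, and the sex-linked genes 0.731. Median, mean and test direction differed in sign for the megakaryocyte, stroma, immediate early and several other uncalled lists, whose values on the TPM scale were positive while camera placed them below other genes.

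By camera with preset correlation 6 of 30 lists were called, and with the replicate block 6. With an estimated correlation 0 were called after adjustment and 3 had an unadjusted p under 0.05, and fry, which tests a list without reference to other genes, called 0 by direction or by change either way. The labels call the experiments independent but do not say how many mice each library held. The limma p-values therefore rest on the spread between these libraries, moderated over genes, and not on a spread between mice. Camera with its preset correlation treats the genes of a list as nearly independent, so its p-values do not measure the spread between libraries.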

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

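The corrections for length and GC, the covariates, the removal of rRNA-like or identical rows and the estimated correlation with the block were tests chosen only after the result was seen. The count of 4 genes was 0 without a filter, 1 after median-of-ratios scaling, 1 after quantile normalization, 0 without the trend, 1 with the robust prior, 16 with array weights and 7 at an adjusted p under 0.1. At an unadjusted p under 0.05 limma gave 535 higher and 213 lower genes without a filter and 457 and 148 without the trend. With the transcript length trend removed the count of genes that passed was 2, with or without the replicate block (2), and with the GC trend removed and the replicate block 9. Hbb-b2 was not among the genes with a length, so the length and GC fits did not test it. Its copy Hbb-bt passed in them, and Ccl3 lost its call with the length trend removed. Leaving out 1 library gave 0 (db/db replicate 2) to 16 (WT replicate 1). The cause was not tested, except that fewer libraries enter a leave-out. In the paired fit with the replicate block it was 6, which included the 4, and beyond Rps27rt and Myl10 the block changed no other call among the named genes and called lists. The remaining 13 of 25 alternatives stayed within 1.5 times of 4. Gfi1 kept its direction and did not pass in any of 24 alternatives (log2 fold change 1.38 to 1.97, adjusted p 0.0633 to 0.9999), nor did Lepr in 23 (-0.45 to -0.19). The count of 6 lists was 0 with an estimated correlation, 0 by fry, 0 with an estimated correlation and the replicate block, and 3 (WT replicate 3) to 9 (WT replicate 1) with 1 library left out. No named gene reversed, and no called list by its test. TPM carries no depth, so whether low genes such as Lepr and Gfi1 are limited by read counts is unknown.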

Other observations

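The Gimap, Eno1 and sex-linked values, the globin tests, the corrections for length and GC, the granule-score and size-factor covariates, the shortened progenitor list and the splits after scaling were tests chosen only after the result was seen. Gimap genes encode GTPases that act in lymphocyte survival. They were looked at because Gimap3 was among the named genes, so Gimap3 was left out of the counts. Of 7 other measured members, 5 had positive fold changes, and 3 were higher and 0 lower at an unadjusted p under 0.05. Their median of 0.33, against 0.18 for all genes, was not past the threshold by camera (unadjusted p = 0.183). Gimap4 was 5.65 ± 2.03 TPM in WT and 13.7 ± 1.39 TPM in db/db, Gimap7 was 3.56 ± 2.95 and 10.1 ± 4.09 TPM, and Gimap6 was 210 ± 99.4 and 318 ± 69.0 TPM (SD, n = 3 each). Gimap1, the second of the abundant members, was 263 ± 51.2 and 237 ± 76.0 TPM.

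The glycolytic enzyme gene Eno1 was 132 ± 70.2 TPM in WT and 257 ± 37.1 TPM in db/db, while its near-identical copy Eno1b was 152 ± 38.8 and 90.9 ± 36.0 TPM. Because reads can be divided between them, the sum is the safer value, 285 ± 31.7 and 348 ± 34.9 TPM (SD, n = 3 each), a mean log2 difference of 0.29 (SE 0.10). Both libraries of experiment 2 listed the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y at 0 and had the highest Xist values, 243 TPM in WT and 445 TPM in db/db. The 4 libraries of experiments 1 and 3 listed each of these Y-linked genes between 1.11 and 20.8 TPM and Xist between 107 and 188 TPM, so these zeros followed the experiment and not the genotype. Within experiments 1 and 3, however, Ddx3y, Kdm5d and Uty were higher in db/db, and Xist was lower, at 107 against 165 TPM and 118 against 188 TPM. Eif2s3y was higher in db/db in experiment 3, at 20.8 against 5 TPM, and lower in experiment 1, at 2.39 against 3.33 TPM. A share of male cells that differed between the genotypes in these experiments is thus not excluded.

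Hbb-b2 was called as higher in db/db HSCs. Red-cell precursors, which the red-cell antibody of the sort was there to remove, would bring alpha-globin along. Hba-a1, the 1 alpha-globin symbol above 0, differed by a mean log2 of 0.35, below Hbb-b2 by 2.58 (SE 0.93). This gap exceeded 2 SE, a lenient rule for 3 experiments, so it argues only weakly against them as the source of Hbb-b2. Rhag, a red-cell gene that did not pass over all genes, differed by 1.85, 1.82 and 1.84 in the 3 experiments, as such cells would also give. A shift of reads between near-identical beta-globin genes fails as an explanation, since their sum rose by a mean log2 of 2.82 (SE 0.52). Red-cell precursors are thus not excluded. The other candidate explanations left open are a beta-globin variant that happened to differ between the mice and a change in the HSCs of obese mice, neither of them tested. Under median-of-ratios scaling and quantile normalization the log2 fold change of Hbb-b2 stayed at 2.73 and 2.80, from 2.93, while its call ended (adjusted p = 0.36 and 0.198, in a range over alternatives of 4.82e-05 to 0.890).

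Gfi1 had a positive fold change that did not pass (limma adjusted p = 0.435). The progenitor and granulocyte lists were called as higher, though not by camera with an estimated correlation (adjusted p = 0.443 and 0.845, in ranges over alternatives of 2.34e-05 to 0.899 and 1.71e-12 to 0.933). All of these would also follow if more granulocyte RNA reached the db/db libraries, although the sort was meant to exclude its source cells. With the score of the 5 granule genes as a covariate, the log2 fold change of Gfi1 was 1.97 (SE 0.57, limma adjusted p = 0.425, in a range over alternatives of 0.0633 to 0.9999). It stayed above 0 by more than 2 SE, and the relative median of the progenitor list stayed at 0.40 (camera adjusted p = 0.0209), or at 0.31 (adjusted p = 0.0187) without Mpo and Ctsg, which stand on the granulocyte list too, from 0.29. For Gfi1 this argues against RNA that follows these 5 granule genes as the whole source. The progenitor list did not shrink either, but its p-values come from camera with its preset correlation. They do not measure the spread between libraries, so they do not decide the question for that list. RNA of granulocyte cells that do not express the 5 genes is not covered by the score. The granulocyte list holds the 5 score genes and so was not tested by it. A different mix of cells within the gate may explain the progenitor genes and was not tested, since bulk libraries do not resolve cells, and it stays open beside an effect of obesity on each HSC.

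Ribosomal protein genes were called as lower in db/db HSCs, but not with an estimated correlation (adjusted p = 0.845, in a range over alternatives of 5.90e-21 to 0.933) or by fry (0.606), 0 of 82 passed over the list alone, and in experiment 1 their relative median was 0.02 higher in db/db. With the GC trend removed and the replicate block, their relative median stayed at -0.41 (camera adjusted p = 3.15e-11), from -0.42. That size, and not the kept call, argues against GC content, since camera called this list in 7 of the 9 other splits below too. With the length trend removed and the block, their relative median was -0.29 (camera adjusted p = 9.93e-06), so a part played by length cannot be told apart. It was -0.44 after median-of-ratios scaling (adjusted p = 8.15e-11), since 1 factor per library moves the list and all genes about alike, but with the log2 size factor as a covariate it shrank to -0.078 and the call ended (adjusted p = 0.235). The lower values may thus go with library differences, beyond a uniform scaling, that follow the size factor in both genotypes, as in WT replicates 1 and 2 and db/db replicate 1. Because these genes took 22.4% to 33.3% of TPM, a change in them also moves the size factor, so a loss in part of the db/db libraries stays open.

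The 6 libraries can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 4 genes and the highest of the others 3, so 1 split of 10, the real one, gave as many. It gave 6 lists and the highest of the others 9, so 6 of 10 gave as many. Of the 4 splits that part all 3 experiment pairs, the other 3 gave at most 2 genes and between 1 and 3 lists, while the 6 that keep a pair together gave up to 3 genes and between 3 and 9 lists. The ribosomal protein list was called in 7 of the 9 other splits, granulocyte genes in 6, oxidative phosphorylation in 4, interferon and progenitor genes in 2 each, and lymphoid genes in 0. WT replicates 1 and 2 with db/db replicate 1 against the rest gave 2654 genes at an unadjusted p under 0.05, against 638 for the real split, and it parts the size factors (0.815 to 0.915 against 1.13 to 1.23), so a shift shared by all genes enters this count on the TPM scale. After median-of-ratios scaling, which removes that shift, it gave 1317 such genes, against 652 for the real split, and 52 genes past the adjusted threshold, against 1, which points to a structure of the libraries beyond the shift. With the log2 size factor as a covariate, limma called 3 symbols for genotype, all among the 4, and camera 6 lists, 4 of them the same.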
